A study of Homo sapiens with 70 samples.

How the data were processed

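Total RNA of plasma extracellular vesicles from healthy controls was sequenced, with 1 library per donor and 70 libraries in all. Per the labels' protocols, RNA was isolated with the Invitrogen total exosome RNA and protein isolation kit, amplified with the SMART-Seq v4 ultra low input kit and made into libraries with Nextera XT. Per the submitters' processing notes, reads were aligned with STAR to hg19 and counted with featureCounts; versions, annotation and settings are not given in the sources used here. The deposited values are raw read counts per gene symbol, limited to protein-coding genes, with no normalization by the authors. The values are whole numbers and each column has its own total. The kit named in the labels adds no molecular identifiers, so reads are not independent molecules, and intervals across libraries carry amplification noise as well as differences between donors. No strand setting is stated, so reads of a gene and of its antisense partner cannot be told apart.

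The table holds 17938 genes, of which 17927 symbols were found in the reference gene table. The 17 genes located only on the Y chromosome were left out of all values. All other steps used the remaining 17921 genes. No library fell under the depth minimum of 50000 counts and 1000 genes. Library totals ran from 1.91 to 27.1 M counts. In the 2415 pairs of libraries, the lowest chi-square per degree of freedom over genes was 22.0, so no library had been deposited more than once.

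The labels name 1 group, healthy control, and give no batch, pairing or donor detail used here. No comparison between groups was therefore possible, and every result describes levels, spread or relations across the donors. Gene lists were fixed before the data were examined, together with the tests and the rule for named genes. There were 21 lists of markers of blood cells, tissues and processes, and 1 background list of genes of retina, spermatid, enamel, lens, inner ear, pituitary and hair. Of their 389 members, 379 were in the table; GP1BB, CEACAM5, FCGBP, NEFL, NEUROD6, RBP3, PRM1, TNP1, CRYGC and FSHB were not analysed here. Named genes are the 20 with the highest mean CPM, up to 4 members per list with the highest mean CPM, and the colon epithelium, pan-epithelial, WNT target and stromal members with at least 5 counts in 35 or more of the 70 donors. They also include the 10 most and 5 least variable genes with a mean log2 CPM of at least 5, and for each score the 6 genes with the smallest p in each direction. Of the genes this rule picks, 2 are not analysed here. Other genes named in the text were chosen after their values were seen: the remaining globin genes, the HLA genes and their partners, and a few list members given as examples.

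CPM were computed on plain library totals. A list's level is the summed CPM of its members, given as percent of all counts, and a member counts as detected at 5 counts or more. Detection of each list was compared with that of the background list within libraries by a two-sided sign-flip permutation test with 100000 resamples and Benjamini-Hochberg adjustment over the 21 lists. Genes were filtered with filterByExpr and scaled with TMM in edgeR 4.0.16 (R 4.3.3). A list score is the mean over the members past the filter of log2 CPM with a prior count of 2, for lists with at least 4 such members. Scores were related by Pearson and Spearman correlation with two-sided permutation p-values from 100000 resamples, adjusted over all 91 pairs; the smallest p such a test can give is 1e-05. Coherence is the mean correlation between members of a list, set against 10000 random lists of genes of like level (one-sided). Spread between donors is the biological coefficient of variation (BCV) of an intercept-only edgeR fit, and list medians were set against 10000 random lists of like level (two-sided). Each random gene was drawn from the 100 genes nearest in level outside the list. Only 79 genes averaged at least 1000 CPM, so for the most abundant members the match in level was poor. Genes were tested for association with the platelet, erythroid and neutrophil scores, per SD of the score, with the quasi-likelihood test of edgeR, leaving out the members of the score's own list. The SE of a change was derived as its absolute value divided by the square root of the quasi-likelihood F statistic. For another scaling or a subset of libraries the score and its SD were computed anew, so changes per SD there have another unit. A positive value is a higher level at a higher score, written as "rose with" where the Benjamini-Hochberg adjusted p was under 0.05. Scripts used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

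The score association, correlation, sign-flip and coherence tests were first tested on simulated data, and the comparison of spread with random lists was not. For the score association, counts were simulated gene by gene from the mean levels, totals and dispersions of these libraries, with a random score. In 1 such set 100 of 7450 genes were made to change by 0.5 log2 per SD of the score and another 100 by 1 log2 per SD. Of these edgeR recovered 51% and 94%. The simulated counts hold no relation between genes and no clusters of libraries, so false calls from such structure were not tested. The correlation test gave p under 0.05 in 4% of 100 simulations with no relation and in 98% with a true r of 0.5. The sign-flip test gave 0% of 40 with no shift and 100% with a shift of 0.5 SD, and the coherence test 10% of 30 with no shared factor and 100% with one of 0.6 SD.

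Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors or plain library totals in place of TMM, looser or no filtering, the DESeq2 Wald test and limma-trend (limma 3.58.1) in place of edgeR, library size as a covariate, other detection minimums, another background, another prior count, rank correlation, thinned libraries, and leaving out the 5 libraries with the lowest totals. After the data were seen, further alternatives were added. One leaves out 8 libraries under the lower Tukey fence of genes detected or of mean correlation with the others. Another leaves out 11 libraries low in globin transcripts, separated from the other 59 at the widest gap in summed HBA1, HBA2 and HBB levels, and was run with each scaling for the platelet score and for the correlations between scores. The last adds the number of genes detected as a covariate.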

Results

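RNA carried by extracellular vesicles in blood plasma was profiled in 70 healthy donors, with 1 library per donor. Extracellular vesicles are membrane-bound particles that cells release into body fluids. The series asks whether their RNA can be used to follow patients with metastatic colorectal cancer over time, and these libraries are its healthy controls. They set the level from which any cancer-derived transcript would have to be read. Genes are identified by symbol, as in the deposited table of protein-coding read counts.

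Library totals averaged 9.90 ± 4.57 M counts (SD, n = 70), with a median of 8.71 M and a range of 1.91 to 27.1 M. A library held 10839 ± 1750 genes with at least 1 count and 9649 ± 1784 genes with at least 5 counts. When every library was thinned to 1.91 M counts, 9986 ± 1769 genes still had at least 1 count. There were 1034 genes with at least 5 counts in every library and 79 with a mean of at least 1000 CPM. Because the labels give 1 group, all values below describe donors of that group, and p-values measure relations or departures across them. The spread between libraries holds technical differences too, since no donor was measured more than once.

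The libraries fell into 2 clusters by their hemoglobin transcripts. In 11 libraries HBB, the adult beta-globin gene, had a median of 80.9 CPM (range 26.3 to 224), against 61362 CPM (16588 to 264128) in the other 59. HBA2, an alpha-globin gene, had medians of 22.5 and 18738 CPM, and HBD, the delta-globin gene, 0.143 and 230.1 CPM. HBM, the mu-globin gene, lay at 228 and 158 CPM, and ALAS2, the first enzyme of heme synthesis in red cell precursors, at 192 and 291 CPM. The summed level of HBA1, HBA2 and HBB differed 71.4-fold across the gap, and the next largest step between neighbouring libraries was 1.69-fold. The 11 libraries also held fewer genes with at least 1 count (median 8159 against 11500) at higher totals (median 16.4 against 8.26 M). The labels do not name this split, and it was found after the data were seen. Correlations across donors are therefore given within the 59 and within the 11 libraries, with the number of pairs past the threshold over all 70, the planned set.

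Mitochondrial, hemoglobin and cytoskeletal transcripts dominated the protein-coding counts. Non-coding RNA is not in the deposited values, so no share of the whole vesicle RNA can be given. The 20 most abundant genes held 48.6 ± 8.01% of all counts (SD, n = 70), and 9 of them are encoded in the mitochondrial genome. MT-ND1, a subunit of respiratory complex I, led over all 70 libraries with 62704 ± 26102 CPM, followed by HBB with 60972 ± 51413 CPM. This order rests on the 11 low-globin libraries, where HBB reached at most 224 CPM, and without them HBB has the higher mean. The actin-binding thymosin gene TMSB4X reached 51030 ± 16256 CPM and ACTB, beta-actin, 23660 ± 9618 CPM. B2M, the light chain of HLA class I molecules, reached 34623 ± 14089 CPM. The other mitochondrial genes among the 20 were MT-ND2 (34346 ± 14167 CPM), MT-CO2 (33534 ± 21380 CPM), MT-ND4 (27816 ± 16670 CPM), MT-CO1 (25471 ± 14169 CPM), MT-CO3 (19541 ± 10314 CPM), MT-CYB (16247 ± 7963 CPM), MT-ATP6 (15850 ± 7236 CPM) and MT-ND5 (11394 ± 6747 CPM). HBA2 had a mean of 17838 ± 13602 CPM, and the ferritin genes FTL and FTH1 had 11033 ± 2814 and 8792 ± 3339 CPM. The remaining members were PPBP, PF4, TAGLN2 and CAVIN2. HBA1 and HBA2, like HBG1 and HBG2, are near-identical copies, so the division of reads between them is uncertain.

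Among blood cell markers, those of platelets and red cells held the largest mean shares over all 70 libraries. This order was not taken within the 11 low-globin libraries, where HBB had a median of 80.9 CPM. The platelet list took 3.91 ± 1.58% of counts (SD, n = 70), led by the chemokine genes PPBP (14657 ± 6794 CPM) and PF4 (5880 ± 2609 CPM), with CAVIN2 (4818 ± 2081 CPM) and GNG11 (3856 ± 1856 CPM) next. The erythroid list took 8.28 ± 6.65% over all libraries and 9.76% in the 59. HBB had a mean share per library of 62.2% of the list over all 70 libraries, the low-globin libraries included. The neutrophil list took 0.593 ± 0.470%, nearly all from the calgranulin genes S100A9 (3234 ± 2594 CPM) and S100A8 (2214 ± 1971 CPM). The next member, S100A12, had 98.2 ± 83.5 CPM. Marker lists of other leukocytes each stayed near or below 0.0508% of counts. The higher share of the neutrophil list thus rests on S100A9 and S100A8. Whether their reads came from neutrophils alone was not tested. LYZ, the lysozyme gene, led the monocyte list with 201 ± 146 CPM, BANK1 the B cell list with 175 ± 64.5 CPM, LCK the T cell list with 118 ± 71.7 CPM, and GNLY, granulysin, the NK cell list with 95.5 ± 74.4 CPM. MS4A7 (94.7 ± 63.4 CPM) and MS4A6A (50.1 CPM) followed for monocytes, MS4A1 (72.4 ± 50.1 CPM), VPREB3 (38.3 CPM) and BLK (34.3 CPM) for B cells, CD3D (33.5 CPM), CD2 (24.4 CPM) and CD3E (23.96 CPM) for T cells, and NKG7 (66.8 ± 40.4 CPM), CTSW (66.5 ± 53.6 CPM) and GZMB (35.9 CPM) for NK cells. The lists took 0.0508 ± 0.0231% for monocytes, 0.0455 ± 0.0178% for B cells, 0.0392 ± 0.0193% for NK cells and 0.0292 ± 0.0162% for T cells. The endothelial list took 0.0450 ± 0.0141%, and CLDN5, a tight junction gene of endothelium, had a mean share per library of 59.6% of the list.

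**Figure D1:**
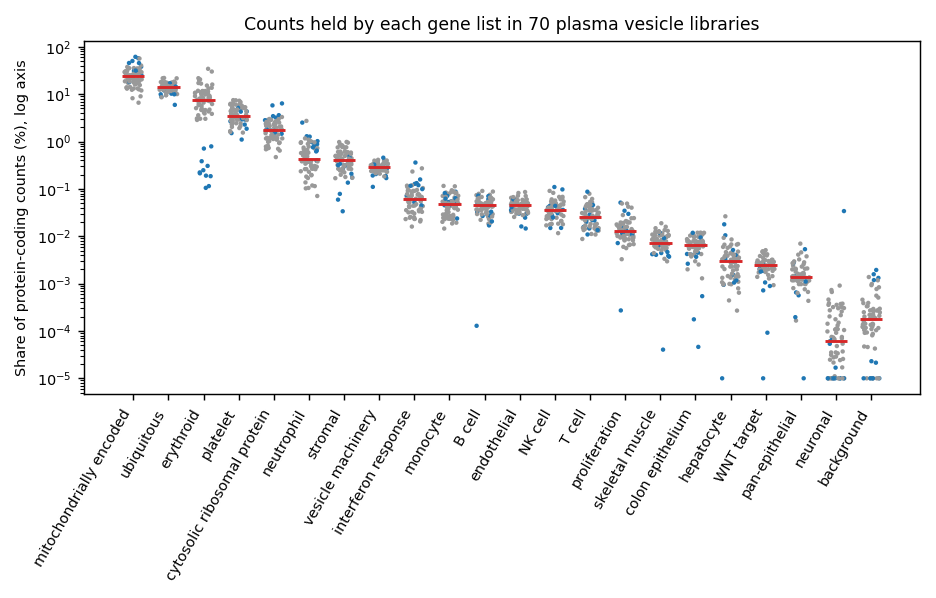
Share of protein-coding counts (percent, log axis) held by each gene list in each of the 70 libraries. Points are libraries, blue for the 11 low-globin libraries and grey for the other 59, with values under 1e-05 drawn at 1e-05, and red bars are medians. The mitochondrially encoded list has the highest mean share (25.7%) and the background list the lowest (0.000313%). By median the neuronal list is lowest (6.25e-05%, against 0.000177% for the background list).

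Lists of general cell functions ranged from mitochondrially encoded to proliferation genes. The 13 mitochondrially encoded genes took 25.7 ± 11.6% of counts and the 15 ubiquitous genes 14.2 ± 3.14%. The 32 cytosolic ribosomal protein genes took 1.93 ± 1.06%, led by RPL3 (1533 ± 837 CPM), RPL13 (1276 ± 609.5 CPM), RPS6 (1141 ± 615 CPM) and RPS19 (1089 ± 587 CPM). Genes of the vesicle machinery took 0.289 ± 0.0607%, with RAB11A, a GTPase of recycling endosomes, at 629 ± 241 CPM and the tetraspanin gene CD9 at 268 ± 161 CPM. HSPA8, a heat shock chaperone, and SDCBP, the syntenin gene, had 502 ± 264 and 371 ± 134 CPM. Interferon response genes took 0.0723 ± 0.0571%, led by IFI27 (195 ± 229.5 CPM), ISG15 (72.5 ± 61.5 CPM), IFIT2 (53.04 ± 59.4 CPM) and OAS1 (50.1 ± 47.3 CPM). Proliferation genes took 0.0160 ± 0.0104%, led by CENPF (32.5 ± 29.5 CPM) and RRM2 (24.6 ± 25.2 CPM).

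Markers of colon epithelium were present at low level in these healthy donors, and few genes carried the signal. The colon epithelium list held 0.00667 ± 0.00289% of counts (SD, n = 70). VIL1, which encodes the brush border protein villin, made up 57.7% of the list's counts as the mean of the shares in single libraries. VIL1 averaged 43.2 ± 29.7 CPM, with at least 5 counts in 64 of the 70 donors. TFF3, the intestinal trefoil factor, averaged 9.34 ± 6.95 CPM (66 donors), CEACAM6, a cell adhesion gene, 7.57 ± 8.45 CPM (57 donors) and FABP1, a fatty acid-binding protein, 1.05 CPM (36 donors). GPA33, a cell surface antigen of intestinal epithelium, averaged 1.59 ± 4.28 CPM (24 donors). Without VIL1 the list held 0.00235% of counts. The pan-epithelial list held 0.00170 ± 0.00116%, mostly from the keratin genes KRT18 (7.56 ± 5.93 CPM, 60 donors) and KRT8 (3.02 ± 3.06 CPM, 58 donors). The WNT target list held 0.00256 ± 0.00103%, led by APCDD1 (12.6 ± 7.83 CPM, 67 donors) and ASCL2 (8.13 ± 6.37 CPM, 64 donors). TDGF1 and PROX1 averaged 1.47 ± 3.27 and 1.23 ± 2.38 CPM. The stem cell gene LGR5, picked as an example after its value was seen, averaged 0.0478 CPM.

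The stromal list stood far higher because of 1 gene. It held 0.439 ± 0.226% of counts, and SPARC, which encodes the matrix protein osteonectin, averaged 4287 ± 2276 CPM. The mean over libraries of SPARC's share of the list was 96.3%. ZEB1, a transcription factor, averaged 57.9 ± 36.3 CPM (68 donors) and COL6A3, a collagen VI chain, 20.6 ± 15.8 CPM (63 donors). TAGLN (5.01 ± 6.32 CPM, 57 donors), DCN (4.22 ± 7.82 CPM, 36 donors) and ACTA2 (2.86 CPM, 45 donors) were lower. Among the other tissue lists, TNNC2, a fast troponin gene, led the skeletal muscle list at 57.8 ± 31.8 CPM, with a mean share per library of 69.1% of the list. ALB, the albumin gene, led the hepatocyte list at 17.3 ± 19.7 CPM. APOA2, APOC3 and APOA1, which encode apolipoproteins, followed at 3.46, 2.47 and 2.22 CPM, and the troponin genes TNNT3, TNNI2 and TNNT1 at 9.25, 4.35 and 4.30 CPM. The neuronal list held 0.000617 ± 0.00406%, raised by STMN2 (at least 5 counts in 3 donors), and its median share was 6.25e-05%.

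Detection was compared with a background of 19 genes that blood and gut are not known to use, such as photoreceptor and spermatid genes. On average 6.77 ± 5.82% of these had at least 5 counts. The colon epithelium list reached 18.1 ± 6.11%, which was 11.3 ± 7.15 percentage points higher (SD of the difference, n = 70) and higher in 66 of the 70 donors. Few members made this margin: VIL1, TFF3, CEACAM6 and FABP1 had at least 5 counts in 91.4%, 94.3%, 81.4% and 51.4% of donors. Many other members, such as CDX2 (4.29%) and KRT20 (1.43%), lay under the background mean. The sign-flip test resamples donors with the lists fixed, so its p-values do not extend to markers of a tissue as a class. The pan-epithelial list reached 22.9 ± 9.997%, the WNT target list 22.1 ± 9.62% and the stromal list 35.3 ± 13.7%, which were above background in 64, 67 and 70 donors. In all, 20 of the 21 lists were above background, each with the smallest p that the sign-flip permutation test can give (1e-05, adjusted p = 1.05e-05 over 21 lists). The neuronal list was the exception, at -1.65 percentage points (p = 0.109, adjusted p = 0.109, lower in 39 of 70 donors). The margins of the colon, pan-epithelial and WNT target lists rest on the choice of background: against the neuronal and skeletal muscle lists together they were -5.48, -0.686 and -1.49 percentage points. At a minimum of 1 count the neuronal list was 2.86 percentage points above background.

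**Figure D2:**
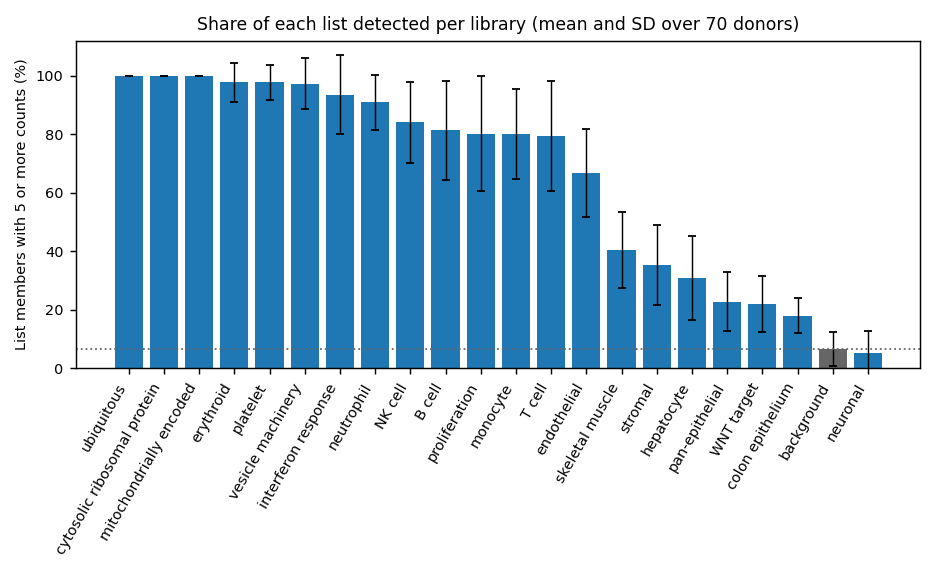
Share of list members with at least 5 counts (percent), as the mean (bar) and SD (error bar) over 70 donors, for the 21 lists and the background list (grey, dotted line at its mean of 6.77%). Blood cell lists lie between 79.4% (T cell) and 97.8% (erythroid), and the colon epithelium list at 18.1%.

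Members of a list varied together most strongly for the mitochondrial, ribosomal protein and platelet lists. Their mean correlation between members across all 70 libraries was 0.912, 0.859 and 0.628, against medians of 0.251, 0.155 and 0.0697 for random lists of like level (adjusted p = 0.000467 for each, permutation over 10000 random lists, 14 lists). For the mitochondrial list the random lists reached under 1000 CPM, so level was matched poorly there. The B cell list (0.440, adjusted p = 0.00735) and the erythroid list (0.270, adjusted p = 0.00924) also exceeded their random lists. Within the 59 libraries 11 of the 14 lists did so, among them the platelet (0.744), erythroid (0.521), neutrophil (0.358), interferon response (0.319), B cell (0.278) and T cell (0.240) lists. The endothelial, vesicle machinery and ubiquitous lists did not, with adjusted p of 0.307, 0.386 and 0.706.

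Set against random lists, the erythroid, platelet, interferon response and mitochondrially encoded lists varied more between donors, and the ubiquitous list less. For very abundant members, such as MT-ND1 and TMSB4X, the genes drawn reached under 1000 CPM. Level was thus matched poorly for the mitochondrially encoded and ubiquitous lists, and part of their departure may reflect level. The common BCV was 0.896 over all 70 libraries and 0.641 within the 59. The median BCV of the erythroid list was 0.846 and that of the platelet list 0.722, above the central 95% of random lists of like level (upper limits 0.663 and 0.661). The interferon response list (0.940, against 0.888) and the mitochondrially encoded list (0.698, against 0.636) also lay above, and the ubiquitous list (0.385) lay below the lower limit of 0.463. Adjusted p over 14 lists were 0.00280, 0.00373, 0.00952, 0.00490 and 0.00373 in that order (permutation over random lists). Within the 59 libraries the neutrophil (0.604) and NK cell (0.676) lists lay above as well and the ribosomal protein list (0.281) below, with adjusted p of 0.0184, 0.0360 and 0.00350.

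Among 2554 genes with a mean log2 CPM of at least 5, the median BCV was 0.604, and 6 of the 10 most variable genes were HLA or globin genes. HLA-C and HLA-B, which encode class I antigen-presenting chains, had BCV of 1.67 and 1.55, and 1.67 and 1.57 within the 59 libraries. The globin genes HBG2, HBD, HBB and HBA1 had BCV of 1.63, 1.23, 1.21 and 1.20 over all libraries, and 1.05, 0.586, 0.519 and 0.531 within the 59. PRRG3, a vitamin K-dependent membrane protein gene, had the largest BCV (1.83), and 3 libraries held 86.8% of its CPM. MTRNR2L1, which shares its sequence with mitochondrial ribosomal RNA, had 1.48, IFI6, an interferon-induced gene, 1.21, and TMEM70, an assembly factor of ATP synthase, 1.19. HLA genes and MTRNR2L1 share reads with similar genes, so their values are uncertain. Among the least variable genes were PFN1, the profilin gene (0.266), ARPC2, a subunit of the Arp2/3 actin nucleator (0.267), HNRNPC, an RNA-binding protein (0.273), and PRR13 (0.284).

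Scores of 14 lists were then related across donors to ask which transcript groups rise and fall together. Monocyte and interferon response genes rose together in both clusters. Within the 59 libraries Pearson r was 0.643 and Spearman rho 0.682 (permutation p = 1e-05 for each, the smallest possible; adjusted p = 0.00013 and 0.000114 over 91 pairs). Without the 2 libraries farthest from the median of the first score r was 0.637, it was 0.696 and 0.581 in the libraries of lower and of higher totals, and within the 11 libraries it was 0.797 (permutation p = 0.00359, adjusted p = 0.0408). The erythroid and proliferation scores rose together as well, with r = 0.496 and rho = 0.430 in the 59 (permutation p = 7e-05 and 0.00087, adjusted p = 0.00049 and 0.0044) and r = 0.817 in the 11 (permutation p = 0.00289, adjusted p = 0.0376). Without the 2 farthest libraries of the 59 this r was 0.375, and it was 0.399 and 0.635 in the libraries of lower and higher totals.

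Ribosomal protein transcripts were lower where platelet transcripts were higher. Within the 59 libraries r was -0.667 and rho -0.667 (permutation p = 1e-05 for each; adjusted p = 0.00013 and 0.000114). It was -0.672 without the 2 farthest libraries, -0.640 and -0.707 in the libraries of lower and higher totals, and -0.494 within the 11, where it did not pass the test (permutation p = 0.119, adjusted p = 0.209). The platelet score also went against the monocyte score (r = -0.508, rho = -0.530, permutation p = 8e-05 and 7e-05, adjusted p = 0.00052 and 0.000455) and the interferon response score (r = -0.481, rho = -0.557, permutation p = 9e-05 and 4e-05, adjusted p = 0.000546 and 0.00028) in the 59. Without the 2 farthest libraries these were -0.499 and -0.471, and in the libraries of lower and higher totals -0.624 and -0.371, and -0.557 and -0.404. Within the 11 libraries both were positive, 0.633 and 0.554, with adjusted p of 0.119 and 0.171. Over all 70 libraries, the planned set, neither passed (adjusted p = 0.301 and 0.531). B cell and ribosomal protein scores rose together in the 59 (r = 0.537, rho = 0.561, permutation p = 3e-05 and 2e-05, adjusted p = 0.000273 and 0.000165, 0.568 without the 2 farthest, 0.522 and 0.657 at lower and higher totals) and not in the 11 (r = -0.328, adjusted p = 0.447), and over all 70 the sign was negative (adjusted p = 0.0147).

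Over all 70 libraries 63 of the 91 pairs passed an adjusted p of 0.05, 43 with positive and 20 with negative r, and within the 59 libraries 25 did, 12 positive and 13 negative, with 10 shared in sign. Within the 11 libraries 11 pairs passed and 33 had an unadjusted p under 0.05. Of the 25 pairs, 24 kept sign and threshold under DESeq2 size factors, and 12 under plain library totals, where 12 were of the opposite sign. On plain totals 85 pairs passed within the 59 (62 positive, 23 negative) and 75 over all 70 (62 positive, 13 negative), and by rank with TMM 34 did over all 70. Within the 59, 11 pairs kept sign and threshold under each of the 3 scalings, and the 6 given above were picked from these after the values were seen. The other 5 were neutrophil with proliferation, T cell with ribosomal protein and vesicle machinery with ubiquitous scores (positive), and mitochondrially encoded with B cell and with ribosomal protein scores (negative). The platelet score with the vesicle machinery and ubiquitous scores did not keep sign across scalings: r was 0.711 and 0.873 with TMM (rho = 0.723 and 0.872, permutation p = 1e-05, adjusted p = 0.00013 for each r; 0.690 and 0.861 without the 2 farthest) and -0.272 and -0.177 on plain totals (adjusted p = 0.0401 and 0.181). Within the 11 libraries these were 0.486 and 0.0371 with TMM (adjusted p = 0.227 and 0.931). The same holds for the vesicle machinery and ribosomal protein scores, at -0.669 and 0.721, and for the mitochondrially encoded and ubiquitous scores, at 0.647 and -0.644.

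**Figure D3:**
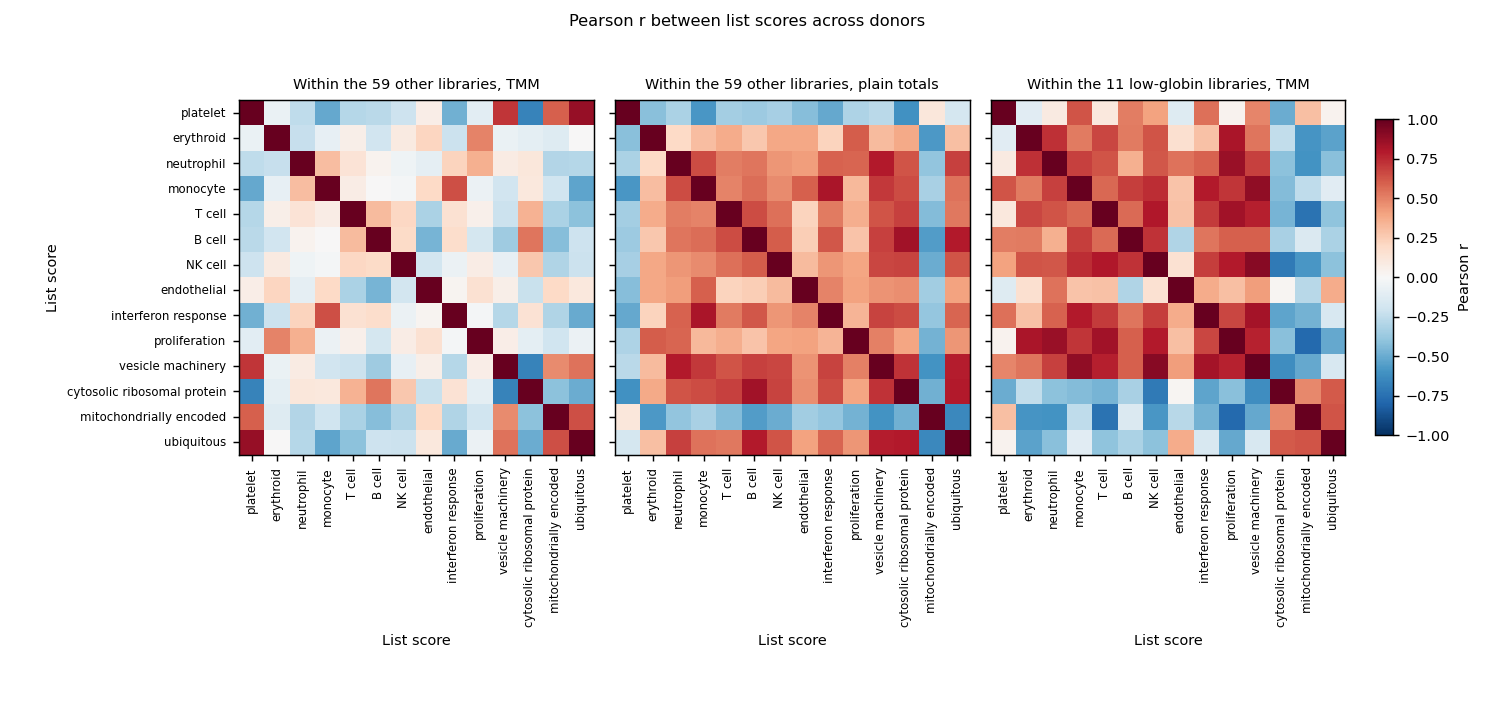
Pearson r between list scores (colour, from -1 to 1) within the 59 libraries under TMM scaling (left), within the same 59 on plain library totals (middle) and within the 11 low-globin libraries (right). The platelet and cytosolic ribosomal protein scores have r = -0.667 on the left, -0.604 in the middle and -0.494 on the right.

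**Figure D4:**
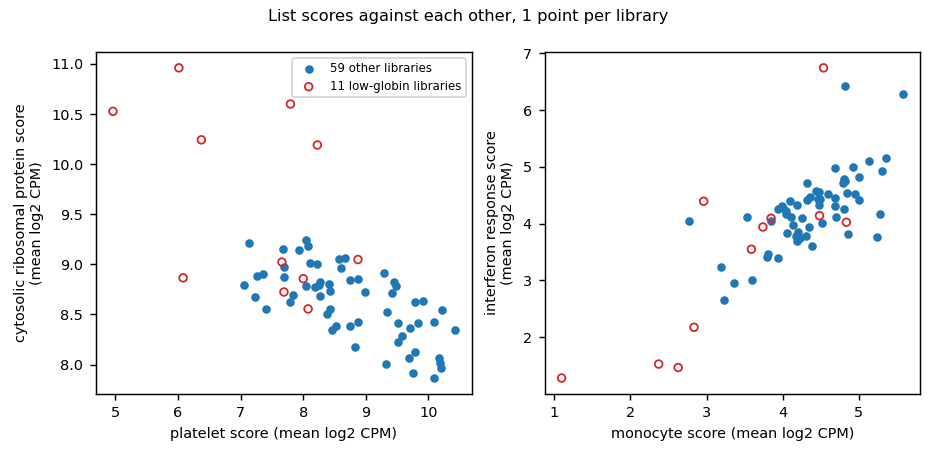
Platelet and cytosolic ribosomal protein scores (left) and monocyte and interferon response scores (right), in mean log2 CPM, with 1 point per library, filled for the 59 and open for the 11 low-globin libraries. Within the 59, r is -0.667 on the left and 0.643 on the right.

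Genes were next tested one by one for the transcripts that follow the platelet score across donors. CTSA, which encodes lysosomal cathepsin A, rose by 1.01 ± 0.05 log2 per SD of the platelet score (SE, n = 70; edgeR adjusted p = 2.24e-29). CLU, the chaperone clusterin, rose by 0.97 ± 0.05, SPARC by 1.02 ± 0.05, SH3BGRL2 by 1.04 ± 0.06, CDKN2D, an inhibitor of cyclin-dependent kinases, by 0.92 ± 0.06, and TPM4, a tropomyosin, by 0.74 ± 0.05. The genes that fell with the smallest p serve several functions. NACA, a subunit of the nascent polypeptide-associated complex, fell by 0.51 on the log2 scale per SD (SE 0.05, edgeR adjusted p = 1.52e-14), PSMB7, a proteasome subunit, by 0.64 and SNRPD2, a core splicing protein, by 0.68. HINT1, a nucleotide hydrolase, fell by 0.54, SSBP1, which binds mitochondrial DNA, by 0.76, and S100A6, a calcium-binding protein, by 0.60. These 12 genes kept their direction and an adjusted p under 0.05 in all 13 alternatives. Within the 59 libraries the first 6 ranged from 0.72 (TPM4) to 0.93 (SPARC), and the last 6 from -0.29 (S100A6) to -0.17 (SSBP1). Sizes within the 59 are per SD of the score among the 59, so they do not share a unit with those over all 70.

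In total 1266 of 7431 genes rose and 1308 fell with the platelet score (edgeR, Benjamini-Hochberg under 0.05), and within the 59 libraries 1595 rose and 1740 fell of 7895. On plain library totals 877 rose and 1561 fell over all libraries, and 821 and 4042 within the 59; limma-trend gave 2929 and 506. The median change of all genes per SD was -0.05 log2 with TMM, -0.12 on plain totals and 0.33 with limma-trend, and in the 59 it was -0.11 with TMM and -0.32 on plain totals. Directions for single genes are called against 0 and not against these medians. A gene counted as risen or fallen can therefore lie on the other side of the median. When the score was permuted inside the 11 and inside the 59 libraries, 12 of 100 permutations called as many genes over all 70 by limma-trend as the real score (3435), so that total holds the difference between the clusters. Within the 59 none of 100 did (3492).

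All 32 cytosolic ribosomal protein genes fell with the platelet score, with a median of -0.46 log2 per SD. The same 32 fell on plain totals, under DESeq2 size factors and within the 59 under each scaling (median -0.24 with TMM), and 32 fell when adjusted over the list alone. RPL3 fell by 0.45 and RPS6 by 0.48 per SD (SE 0.05 for each; edgeR adjusted p = 8e-13 and 1.16e-12). RPS19 fell by 0.43 and RPL13 by 0.34.

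Of the 14 neutrophil genes tested, 7 fell and none rose with the platelet score (7 fell when adjusted over the list alone). S100A8 fell by 0.62, S100A9 by 0.53 and S100A12 by 0.63 per SD, and by 0.35, 0.33 and 0.31 within the 59, where 7 fell and 1 rose. Of the 18 interferon response genes, 5 fell and 1 rose (5 and 1 over the list alone), and 8 fell and 1 rose within the 59. IFIT2 fell by 0.61 and ISG15 by 0.38, while IFI6 rose by 0.97. The IFI6 level was uneven, with 31.5% of its CPM in 1 library and 52.3% in 3 libraries. Of the 10 monocyte genes 2 fell, MS4A7 by 0.61 and FCN1 by 0.40, and of the 10 T cell genes CD3D fell by 0.61. These are also the counts when adjusted over the list alone. Of the 10 NK cell genes 3 fell, NKG7 by 0.45 among them, and CTSW, a cathepsin of cytotoxic cells, rose by 0.96 (4 fell and 1 rose over the list alone). Within the 59, 3 NK cell genes fell and 1 rose, with NKG7 at -0.28 and CTSW at 0.72.

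Vesicle machinery genes went both ways. Of 18, 5 rose and 3 fell with the platelet score (5 and 5 when adjusted over the list alone), and within the 59, 5 rose and 6 fell. CD9 rose by 1.01 ± 0.08, RAB27B, a GTPase of vesicle release, by 0.88 ± 0.11, and RAB11A by 0.49 ± 0.07 log2 per SD, while HSPA8 fell by 0.37 (SE 0.04; edgeR adjusted p = 7.59e-13). These 4 kept their direction on plain totals, where CD9 had 0.85, RAB27B 0.68, RAB11A 0.32 and HSPA8 -0.45. Of the 15 ubiquitous genes 8 rose and 4 fell (the same counts over the list alone), against 6 and 5 on plain totals and 4 and 7 on plain totals within the 59. ACTB rose by 0.74 ± 0.06, FTH1 by 0.66 ± 0.06, B2M by 0.55 ± 0.07 and TMSB4X by 0.43 ± 0.06, while the translation genes EEF1A1 and TPT1 fell by 0.37 and 0.52. Among the most abundant genes TAGLN2, an actin-binding protein, also rose, by 0.77 ± 0.05.

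The 13 mitochondrially encoded genes depended on the libraries and the scaling. Over all 70 libraries 2 rose with the platelet score (1 when adjusted over the list alone), within the 59 all 13 rose with a median of 0.52 log2 per SD, and on plain totals 9 fell over all libraries. On plain totals within the 59 edgeR called 0 of the 13, with a median of 0.02, so their direction is not settled.

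Several of the tissue-list genes found in these vesicles rose with the platelet score. VIL1 rose by 1.57 ± 0.20 log2 per SD (edgeR adjusted p = 2.6e-10) and by 0.995 within the 59. APCDD1 rose by 0.97 ± 0.16, TNNC2 by 0.49 ± 0.11 and the endothelial genes CLDN5 by 0.66 ± 0.08 and EGFL7 by 0.26 ± 0.08, of which EGFL7 did not pass on plain totals (0.17, adjusted p = 0.0733). Within the 59 these had 0.86, 0.77, 0.69 and 0.47. COL6A3 rose by 0.50 ± 0.20 over all libraries (edgeR adjusted p = 0.0432) and had 0.46 on plain totals (adjusted p = 0.131) and 0.18 in the 59 (adjusted p = 0.126). Of the 7 endothelial genes 2 rose and 3 fell (the same over the list alone), with ECSCR down by 0.81, EMCN by 0.46 and NOSTRIN by 0.36. Within the 59 these had -0.12, -0.11 and -0.31 (adjusted p = 0.398, 0.575 and 0.00734), and on plain totals over all libraries all 3 fell.

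Of the 6 genes that rose with the erythroid score with the smallest p, 5 also passed within the 59 libraries. KRT1, a keratin gene, rose by 1.69 ± 0.21 log2 per SD (edgeR adjusted p = 1.1e-09) and by 0.89 within the 59 libraries (adjusted p = 3.26e-08). The SD of the erythroid score over all 70 libraries includes the globin gap, so sizes over all 70 and within the 59 differ in unit. RNF10, a ring finger protein, rose by 0.59 ± 0.06, YBX3, a cold shock domain protein, by 0.44 ± 0.05, TFDP1, a partner of E2F factors, by 0.68 ± 0.10, and GSPT1, a translation termination factor, by 0.63 ± 0.10. Within the 59 these had 0.40, 0.41, 0.35 and 0.47. JUND, a subunit of the AP-1 transcription factor, rose by 0.75 ± 0.11 over all libraries and had 0.11 in the 59 (adjusted p = 0.638). The genes that fell with the smallest p were CLEC2B, a lectin-like receptor (by 0.80), NOP10, a small nucleolar RNP protein (by 0.62), the respiratory chain genes NDUFB3 and COX6C (by 0.68 and 0.55), NEDD8, a ubiquitin-like modifier (by 0.60), and SSBP1 (by 0.67). Of these 6, NOP10 alone passed within the 59, with -0.18 (edgeR adjusted p = 0.0033).

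Over all 70 libraries 605 of 7430 genes rose and 962 fell with the erythroid score, and within the 59 there were 129 that rose and 7 that fell of 7894, with 73 calls shared in sign. On plain totals 2061 rose and 233 fell over all libraries, under DESeq2 size factors 791 and 740, and with limma-trend 4887 and 426. The median of all genes was 0.07 log2 with TMM, 0.27 on plain totals, 0.11 under DESeq2 size factors and 0.54 with limma-trend. Of the 32 ribosomal protein genes 31 fell (32 over the list alone), of the 13 mitochondrially encoded genes 10 (12), of the 14 neutrophil genes 8 (9) and of the 18 interferon genes 7 (9), against 4, 13, 1 and 3 that fell on plain totals and 29, 10, 8 and 7 under DESeq2 size factors. Examples are RPS6 (fell by 0.38), MT-CO2 (fell by 0.51) and IFI27 (fell by 0.73). Within the 59 edgeR called 0 of the ribosomal protein and 0 of the mitochondrial genes, 1 neutrophil and 1 interferon gene, out of 441 genes at an unadjusted p under 0.05 in all. The interferon gene was IFI6, which fell by 0.69 in the 59 (edgeR adjusted p = 3.76e-05) and by 0.84 over all libraries. Of its CPM over all 70 libraries, 3 libraries held 52.3%. For the ribosomal protein and mitochondrially encoded genes, no fall passed without the 11 libraries.

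The genes that rose with the neutrophil score with the smallest p were GCA, MNDA, MSRB1, NCF4, LTA4H and JAML. GCA, the calcium-binding protein grancalcin, rose by 0.44 ± 0.06 log2 per SD (edgeR adjusted p = 1e-05), MNDA, a myeloid nuclear antigen, by 0.41 ± 0.07 and NCF4, a subunit of the phagocyte NADPH oxidase, by 0.35 ± 0.08. MSRB1, a methionine sulfoxide reductase, rose by 0.46 ± 0.09, LTA4H, an enzyme of leukotriene B4 synthesis, by 0.41 ± 0.09 and JAML, an adhesion molecule of leukocytes, by 0.51 ± 0.12. All 6 kept direction and threshold in the 11 alternatives run for this score, and within the 59 they ranged from 0.25 (LTA4H) to 0.49 (GCA). The genes that fell with the smallest p were INTS4, FLT3LG, BEX4, RBMXL1, ACSL6 and TMUB2, by 0.51 (BEX4) to 1.20 (ACSL6). None of these 6 passed within the 59, where edgeR adjusted p ran from 0.205 to 0.946.

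With the neutrophil score 26 of 7436 genes rose and 197 fell over all libraries, and 85 rose and 57 fell of 7900 within the 59, with 34 calls shared in sign. Scaling moved the split: 3405 rose and 83 fell on plain totals, 39 and 131 under DESeq2 size factors, and 250 and 28 with limma-trend. The median of all genes was 0.01 log2 with TMM, 0.36 on plain totals and 0.14 with limma-trend. Of the 13 mitochondrially encoded genes 8 fell (13 when adjusted over the list alone), MT-ND5 by 0.45 and MT-ND4 by 0.41, and on plain totals 13 fell. Within the 59 these had -0.27 and -0.37 with adjusted p of 0.156 and 0.0629, and edgeR called 0 of the 13, with 1363 of all genes at an unadjusted p under 0.05.

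The number of genes detected and 3 of the 14 list scores were related to library total over all 70 libraries, and within the 59 none of these was. The 3 scores were platelet, erythroid and endothelial (adjusted p = 0.0366, 0.0471 and 0.0366 over all libraries; by rank 0.118, 0.0842 and 0.0565, past no threshold), whose r within the 59 was -0.113, 0.0785 and -0.0773 (permutation p = 0.399, 0.554 and 0.562, adjusted p = 0.674, 0.702 and 0.702). Within the 59 libraries no list score and not the number of genes with at least 1 count was related to log10 library total among the 15 measures at an adjusted p of 0.05, and 1 score, interferon response, had an unadjusted permutation p of 0.0489 (r = 0.257). The number of genes had r = 0.150 there (permutation p = 0.258, adjusted p = 0.644). Over all 70 libraries it fell with the total (r = -0.384, rho = -0.255, permutation p = 0.00109 and 0.0335, adjusted p = 0.0163 and 0.118). The 11 libraries had the higher totals and fewer genes.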

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

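The alternatives that leave out the 8 libraries standing apart or the 11 low-globin libraries, those that join the latter with another scaling, and the number of genes detected as a covariate were chosen after the data were seen. The others were planned. For 321 results 2378 alternative values were computed. Of these 2103 stayed the same: direction and side of the threshold for a test, within 1.5 times for a count or a BCV, within 1 SD for a level. Another 171 were weaker (no longer past the threshold, or a count lower by more than 1.5 times), 61 were stronger (newly past it, or a count higher by more than 1.5 times), 16 levels or BCV moved out of the stated range and 27 reversed. Leaving out 8 or 11 libraries, or those with the lowest totals, cannot move a mean level by 1 SD between donors. For levels, these alternatives could only count as the same, so they are no test of the levels. The 2103 include them. No paired analysis was possible because each donor gave 1 library and the labels name 1 group.

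List levels, BCV and detection changed as follows. Without VIL1, its member of highest mean CPM, the colon epithelium list took 0.00235% of counts. Without their own such members the endothelial list took 0.0172%, the WNT target list 0.00130%, the stromal list 0.0102%, the skeletal muscle list 0.00235%, the vesicle machinery list 0.227% and the ubiquitous list 9.12% of counts. With totals taken without mitochondrially encoded genes the endothelial, vesicle machinery and ubiquitous lists took 0.0610%, 0.390% and 19.4% of counts. BCV was 1.05 for HBG2, 0.586 for HBD, 0.519 for HBB, 0.531 for HBA1 and 0.166 for ARPC2 without the 11 libraries, and 0.425 for HNRNPC on plain totals. The neuronal list minus background was 2.86 percentage points at a minimum of 1 count. With the neuronal and skeletal muscle lists as background, the colon epithelium, pan-epithelial and WNT target lists were at -5.48, -0.686 and -1.49 percentage points, since skeletal muscle members are detected more often than the background genes.

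The relations between list scores depended on which libraries were used, on the scaling and on the kind of correlation. On plain library totals 75 of the 91 pairs passed, 13 of them negative, and rank correlation gave 34 pairs, 20 of them positive. Without the 8 libraries 25 pairs passed, 11 of them positive. Without the 11 libraries it was 25 with TMM (12 positive, 13 negative), 25 under DESeq2 size factors (11 positive) and 85 on plain totals (62 positive, 23 negative). Platelet and erythroid scores had r of -0.0107 without the 8 libraries, and without the 11 -0.0674 with TMM, -0.418 on plain totals and -0.0778 under DESeq2 size factors. NK cell and vesicle machinery scores had -0.0881 without the 8, and without the 11 -0.0810 with TMM and -0.102 under DESeq2 size factors. B cell and ribosomal protein scores had 0.152 on plain totals and 0.227 by rank over all libraries, 0.470 without the 8, and without the 11 0.537 with TMM, 0.838 on plain totals and 0.541 under DESeq2 size factors. Mitochondrially encoded and ubiquitous scores had -0.752 on plain totals, and -0.644 there without the 11. On plain totals without the 11, platelet scores had -0.272 with vesicle machinery and -0.177 with ubiquitous scores, and vesicle machinery and ribosomal protein scores had 0.721. These alternatives use fewer libraries, another scaling or ranks, and beyond that the cause was not tested.

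Coherence was past the threshold for 11 lists without the 8 libraries and 11 without the 11, and spread unlike the random lists for 8 and 8. Library total was related to 1 list score on plain totals, 0 without the 8 and 0 without the 11 (with 1 at an unadjusted p under 0.05 by permutation in the latter). Its r with genes detected was -0.134 without the 8 and 0.150 without the 11, and with the erythroid score 0.0785 without the 11.

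For the platelet score limma-trend gave 2929 positive and 506 negative genes, and plain totals without the 11 libraries gave 4863 (821 positive, 4042 negative); the cause was not tested. COL6A3 had -0.0937 log2 per SD in the latter.

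For the erythroid score the total was 2862 with no filter (1330 positive, 1532 negative), 2376 with the DESeq2 Wald test (1389 positive) and 5313 with limma-trend (4887 positive, 426 negative). Plain totals gave 2061 positive and 233 negative. It was 316 without the 8 libraries (145 and 171), 136 without the 11 (129 and 7), and 801 with genes detected as covariate (163 and 638). ACTB had -0.00331 log2 per SD without the 11. With no filter more genes and without the 8 or 11 fewer libraries were used, and for the other changes the cause was not tested.

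For the neutrophil score plain totals gave 3488 genes (3405 positive, 83 negative), the loose filter 338 (309 negative) and no filter 1308 (266 positive, 1042 negative). The DESeq2 Wald test gave 343 (82 positive), limma-trend 250 positive and 28 negative, and DESeq2 size factors 131 negative. With library size as covariate 14 were positive, and with genes detected as covariate there were 99 (78 negative). Without the 8 libraries it was 142 positive and 118 negative, and without the 11 142 in all (85 and 57), where FLT3LG had 0.0201 log2 per SD. The looser filters test more genes, and for the others the cause was not tested.

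Depth limits the genes of low level. Thinned to 1.91 M counts a library held 8225 genes with at least 5 counts, against 9649 at full depth. On simulated data edgeR recovered 51% of genes that changed by 0.5 log2 per SD and 94% at 1 log2 per SD.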

Other observations

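The tests of red cell vesicles, of globin depletion, of transcript length for the globins, of HLA type and those of the tissue-list genes, lists against the platelet score included, were chosen after the result was seen. The other tests below were written down before it. The labels name 1 group, so no biological explanation was tested by comparing groups.

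Fetal and minor globin genes were present beside the adult ones. HBD averaged 226 ± 248 CPM (SD, n = 70), HBM 227 ± 215 CPM and HBQ1, the theta-globin gene, 58.6 ± 32.1 CPM. The gamma-globin genes HBG2 and HBG1, used mainly before birth, averaged 167 ± 240 and 21.8 ± 34.6 CPM, with at least 5 counts in 60 and 59 donors. The embryonic genes HBE1 and HBZ averaged 0.954 ± 1.40 and 0.660 ± 1.12 CPM, with at least 5 counts in 30 and 22 donors. Reads shared between near-identical copies leave the split within the alpha and gamma pairs uncertain.

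In 11 libraries the globins HBA1, HBA2, HBB, HBD, HBG1 and HBG2 lay far under the other 59, by log2 differences of -9.26 to -6.20. A lower content of red cell vesicles would lower other red cell transcripts about as far. The 16 other erythroid members had a median difference of -0.35 (range -2.90 to 1.53), above the median of all genes (-1.57), which argues against it. A step that removes these globin transcripts is a candidate explanation: 0 of the 16 others lay as low as the highest of the 6 globins. The protocols in the labels name no such step, and whether the 11 libraries were made apart from the others is not stated.

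The difference between the 11 and the 59 libraries was also related to transcript length. Across 7314 genes the log2 difference fell with length (Spearman rho = -0.346), from a median of -0.60 in the shortest 25% to -1.92 in the longest, while rho with GC content was -0.0616. This may reflect shorter RNA fragments or another library preparation, which the data cannot separate. The level of the genes was not held fixed in this relation, so its part in it was not tested. Length does not account for the globins, since all 6 are in the shortest 25% of transcripts and the highest of them (-6.20) lies far below the 2.5th percentile of that group (-3.40).

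The levels of some antigen presentation genes, picked after their values were seen, follow. HLA-E averaged 487 ± 285 CPM, CD74, the class II invariant chain, 400 ± 194 CPM, HLA-B 316 ± 530 CPM and HLA-C 108 ± 182 CPM. HLA-DPA1 averaged 72.6 ± 70.5 CPM and HLA-DRA 54.2 ± 155 CPM. The medians were 408, 381, 63.5, 8.91, 57.5 and 1.09 CPM in the same order, and HLA-DRA had under 5 counts in 22 of 70 donors.

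Classical HLA genes differed between donors far more than genes of like level. The median BCV of 7 polymorphic genes (HLA-B, HLA-C, HLA-DRB1, HLA-DRB5, HLA-DQA1, HLA-DQB1 and HLA-DPB1) was 1.547, against 0.775 for random lists (upper limit of the central 95%, 0.978), and that of 8 partners of low polymorphism 0.674 against 0.675. A candidate explanation is that reads of HLA types unlike the reference are lost or assigned to other genes. HLA-DRA, with low polymorphism and a BCV of 1.94, is an exception that it leaves open. The HLA-C counts did not rise with the interferon response score, with r = -0.193 (95% interval -0.409 to 0.0439) over all libraries and -0.228 within the 59. This argues against interferon as the driver of the spread in these counts. If reads of some HLA types are lost, the counts do not measure HLA-C expression, and its relation to interferon stays open. Among the partners CD74 and HLA-DMB rose with the score (r = 0.509 and 0.393, permutation adjusted p = 0.00015 and 0.0078). The remaining partners ran from -0.189 (HLA-DRA) to 0.131 (HLA-F).

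Genes of tissue lists such as VIL1, SPARC and TNNC2 were found in most donors. Reads of genomic DNA stay open for the lists as a whole: the median over all 111 members was 0.354 CPM, between the median (0.0475) and the highest (0.873) of the background genes, and 42 members lay over the highest. The leading members lay at least 8.66 times over it. RNA shed from colon epithelium would bring the list's other members along, yet the median of the 27 others was 0.0702 CPM, 0.162% of VIL1. Platelets are a possible source: 5 of 14 members rose with the platelet score (35.7%), against 1261 of 7417 other genes, and 0 fell by edgeR. The one-sided Fisher p was 0.0745, and 0.335 within the 59 libraries (4 of 13, with ZEB1 falling by 0.19, adjusted p = 0.0340). For the lists as a set, this cannot be told apart from a chance excess with 14 members. The Fisher test takes genes as independent. It does not bear on the relations of single genes, such as SPARC and VIL1, given above.

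The summed levels of the tissue lists, on plain library totals, were compared with the platelet score with and without each list's leading gene. In the 59 libraries r was 0.866 for the stromal list (rho = 0.870, permutation p = 1e-05, the smallest possible, adjusted p = 3.5e-05 over 14 relations; 0.860 without the 2 farthest libraries) and 0.353 for the colon epithelium list (rho = 0.331, permutation p = 0.00572, adjusted p = 0.0100; 0.333). Without SPARC and VIL1 these were -0.701 and -0.575 (rho = -0.729 and -0.584, permutation p = 1e-05, adjusted p = 3.5e-05 for each). The skeletal muscle list went from 0.334 to -0.416 without TNNC2 (adjusted p = 0.0150 and 0.00229), the endothelial list from 0.287 to -0.535 without CLDN5 (adjusted p = 0.0364 and 3.5e-05) and the WNT target list from 0.195 to -0.463 without APCDD1 (adjusted p = 0.162 and 0.000756). The hepatocyte list had -0.407 with and -0.299 without ALB (adjusted p = 0.00244 and 0.0296), and the pan-epithelial list 0.0887 and 0.0820 (adjusted p = 0.538 for each). Most genes went against the platelet score on plain totals within the 59 (median -0.32 log2 per SD), so these values settle no source.

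Chance alignment of genes with the scores was tested by limma-trend with 100 permutations each. With all 70 libraries 0 permutations called as many genes as the real platelet (3435, highest other 518), erythroid (5313, highest other 389) and neutrophil score (278, highest other 1). These permutations break up the 11 and the 59 libraries. With scores permuted inside the 11 and inside the 59, 12 called as many genes as the platelet score (highest other 4178), so chance cannot be excluded for that total. It was 0 for the erythroid score (highest other 5128) and 0 for the neutrophil score (highest other 2). The high counts of these permutations for the platelet and erythroid scores point to the structure of the libraries. Among the 59 libraries alone 0 called as many as the real platelet (3492, highest other 0), erythroid (138, highest other 38) and neutrophil scores (194, highest other 1). With 100 permutations, chance totals of this size are thus rare there. This covers the totals by limma-trend and not the single genes named by edgeR.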
